A study of Caenorhabditis elegans with 20 samples.

How the data were processed

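Gene expression was measured on Affymetrix C. elegans arrays in 20 samples of whole worms collected on adult day 4. Per the labels, the worms were grown at 20 °C with FUDR, a drug that blocks the production of progeny, added from the start of adulthood. They were fed since hatching on HT1115 bacteria (the strain name as the labels give it) that carried either an empty vector or a vector for RNAi against tax-6, and total RNA was extracted from the whole body with Trizol. Biotinylated cRNA was made from 6 ug of RNA. The 10 groups held 2 arrays each. The labels do not say whether the 2 arrays of a group came from separate cultures, so the spread within a group may be technical. Every p-value measures the spread between these samples only.

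The deposited values are log2 expression values per probe set, which the authors summarised and normalized between arrays with RMA in the affy package; versions are not given in the sources used here. The table held 22625 probe sets. The median per array lay between 5.7 and 5.89, and values ran from 2.43 to 14.39. Of the probe sets, 77 Affymetrix controls were left out. A probe set was tested where its value lay above 4.45, the 30th percentile of all values, in at least 2 arrays, which kept 17298 of 22548. Probe sets were matched to gene symbols through the platform annotation: 20766 named 1 gene, 887 named several and 972 named none. Where 1 probe set per gene was needed, the one with the highest mean over all arrays was taken among those that name 1 gene, which gave 13223 genes. Positions of the probes along their transcripts were not analysed here. Array signal has no read depth. The number of arrays limits the precision, and dim probe sets may lie close to the background, which was not measured here.

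The log2 values were fitted with limma 3.58.1 in R 4.3.3. All 20 arrays shared 1 fit with a mean per group, so that each probe set's spread came from 10 residual degrees of freedom and was moderated with 8.4 prior degrees of freedom. The average effect of tax-6 RNAi came from a second fit on the 16 arrays of the 4 strains given both foods. That fit had strain and RNAi as additive terms and 11 residual degrees of freedom. Its residual spread holds differences of the RNAi effect between strains as well as differences between arrays of a group. Tests were two-sided and p was adjusted by Benjamini and Hochberg over the 17298 probe sets of a comparison, with 0.05 as the threshold. There were 18 comparisons, of which 5 were interactions, tests of a difference between 2 effects. An exact permutation test of 2 arrays against 2 cannot give a p under 0.333, so no single comparison was tested that way.

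A total of 36 gene lists, the comparisons, the tests, the alternatives and the rule for named genes were chosen before the data were examined. Each list was tested in 13 comparisons with camera of limma, with the preset correlation between genes of 0.01, and p was adjusted over the lists of 1 comparison. The same test with a correlation estimated from the residuals is given beside each call. A member counted as risen or fallen where its own adjusted p over all probe sets passed the threshold; a second count used a p adjusted over the list alone. Named genes were, for each comparison, the 8 largest rises and 8 largest falls past the threshold with no overlap between the arrays of both groups (5 and 5, without that condition, for an interaction), the 4 members of a described list with the smallest adjusted p, and daf-2, rsks-1, aak-2 and tax-6 as checks of the labels. Of the values of these 4 genes, those that check a label are given, and those of every other comparison of 2 groups in which a probe set of the gene passed; this selection was made after the values were seen. The ranking by size took only genes with a symbol of letters and a number, such as cpr-2, and left out sequence names such as T12D8.5. Standard errors of a gene are those of the fitted log2 change. The standard error of a list median comes from the spread of the changes across its genes, taken as independent, and not from the spread between arrays.

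The fit was tested on simulated data with the N2 means and each probe set's own residual spread, with genes drawn independently and 200 of 17298 probe sets changed. For daf-2 against N2, 35.8% of changes of 0.5 on the log2 scale, 95.5% of changes of 1 and 100% of changes of 2 were recovered, with 8 false calls. For the average RNAi effect, simulated as the same change in all 4 strains, 89.6% of changes of 0.5 were recovered, with 13 false calls. Differences of the effect between strains, which this fit counts as spread, were not simulated, so recovery in the data may be lower. For the tax-6 RNAi by daf-2 interaction, 67.2% of changes of 1 were recovered, with 7 false calls. A shift of 0.3 in a list of 54 genes was found by camera in 20 of 20 simulations, and 0 of 700 tests of other lists passed. Since the genes were drawn independently, this cannot show how often camera calls lists falsely where genes are correlated.

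The alternatives were no filter on dim probe sets, a filter at the 50th percentile, cyclic loess applied again to the deposited values, the replicate number as a block, moderation with an intensity trend and robust settings, a fit of only the arrays compared, and leaving out each array in turn. The lists were also tested with the mean of all probe sets of a gene. A fit without the arrays labelled aak-2 o/e; daf-2 rsks-1, and a fit of the average RNAi effect on 8 group means, were added after the data were seen. Correlations between effects were computed across genes, which are not independent replicates, only for pairs of effects that share no array.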

Results

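The data hold log2 expression values for whole C. elegans on adult day 4 in 20 arrays, as 10 groups of 2. The series asked how expression changes under single, double or triple perturbations of regulators in the AMPK, insulin and TOR pathways. The strains were wild-type N2, daf-2 (a mutant of the insulin-like receptor), rsks-1 (a mutant of the S6 kinase that acts in the TOR pathway), the double mutant daf-2 rsks-1, a strain labelled aak-2 o/e (overexpression of a catalytic subunit of AMPK) and the triple combination labelled aak-2 o/e; daf-2 rsks-1. All 6 strains were measured on empty-vector bacteria, and the first 4 also under RNAi against tax-6, which encodes the catalytic subunit of calcineurin. Arrays of the same group correlated at 0.9938 to 0.9962 across tested probe sets, and arrays of different groups at 0.9383 to 0.9913. The first principal component held 28.1% of the variance and the second 25.8%. Where the mean of a group lay under the filter value of 4.45, the signal there was low and the size of a change is uncertain. Such genes are named. The filter value is not a measured background level. Changes of genes below are log2 changes with their standard error (SE), with n = 2 arrays per group unless stated.

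The genes named in the labels were read first. The tax-6 probe set fell by 0.65 in N2 under tax-6 RNAi (SE 0.12, adjusted p = 0.00101), by 0.96 in rsks-1 (adjusted p = 1.56e-05) and by 0.41 in daf-2 rsks-1 (adjusted p = 0.0287), each with the same SE, which holds for a probe set in every comparison of 2 groups. In daf-2 its log2 change was -0.37 (adjusted p = 0.0535), and with the replicate number as a block in limma adjusted p = 0.0487. With a trend and robust moderation in limma the daf-2 rsks-1 value had adjusted p = 0.0568. Levels of tax-6 were low, between 4.5 and 5.46, near the filter value of 4.45. Over the 4 strains tax-6 fell by 0.60 (SE 0.08, n = 8 arrays per arm, adjusted p = 9.61e-05), and had adjusted p = 0.0521 in limma on the 8 group means, a fit added after the data were seen. The tax-6 probe set was also lower in the arrays labelled aak-2 o/e, with no tax-6 RNAi, where it fell by 0.50 (adjusted p = 0.0201; adjusted p = 0.0605 in limma when only the compared arrays were fitted). On empty vector it also fell by 0.50 in the arrays labelled aak-2 o/e; daf-2 rsks-1 against N2 (adjusted p = 0.00232), and it fell by 0.36 in daf-2 rsks-1 against rsks-1 (adjusted p = 0.037). The last call was lost in limma after cyclic loess (adjusted p = 0.0793), with trend and robust moderation (adjusted p = 0.0757) and with only the compared arrays (adjusted p = 0.0728).

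Both aak-2 probe sets ran against the label of overexpression. In the arrays labelled aak-2 o/e, the brighter one fell by 0.82 against N2 (SE 0.18, adjusted p = 0.0104) and the dimmer one fell by 0.52 (SE 0.14, adjusted p = 0.0292; adjusted p = 0.0736 in limma when only the compared arrays were fitted). In the arrays labelled aak-2 o/e; daf-2 rsks-1, the changes in aak-2 against N2 were 0.32 (adjusted p = 0.151) and -0.48 (adjusted p = 0.00698). Against daf-2 rsks-1 they were -0.24 (adjusted p = 0.331) and -0.30 (adjusted p = 0.11). The brighter probe set also rose over N2 where no overexpression is labelled, by 0.72 in daf-2 (adjusted p = 0.00769), by 0.54 in rsks-1 (adjusted p = 0.021) and by 0.57 in daf-2 rsks-1 (adjusted p = 0.0191). The dimmer one changed there by 0.08 (adjusted p = 0.739), 0.01 (adjusted p = 0.949) and -0.19 (adjusted p = 0.314). The single rsks-1 probe set was higher, not lower, in the arrays labelled rsks-1, by 0.37 (SE 0.12, adjusted p = 0.0194). It was higher than in N2 by 0.35 both in daf-2 rsks-1 (adjusted p = 0.0287) and in aak-2 o/e; daf-2 rsks-1 (adjusted p = 0.0231). With a trend and robust moderation in limma, these 2 calls had adjusted p = 0.0626 and adjusted p = 0.0537. In daf-2 rsks-1 against daf-2 the rsks-1 change was 0.14 (adjusted p = 0.441). Under tax-6 RNAi the rsks-1 probe set rose in the daf-2 strain, by 0.64 (adjusted p = 0.0016). Of 4 daf-2 probe sets, 2 were too dim to test, and the others changed by 0.22 (SE 0.18, adjusted p = 0.46) and 0.22 (SE 0.19, adjusted p = 0.489) in the arrays labelled daf-2. Against N2 they changed by -0.36 (adjusted p = 0.131) and -0.29 (adjusted p = 0.268) in daf-2 rsks-1, and by 0.13 (adjusted p = 0.591) and 0.03 (adjusted p = 0.901) in aak-2 o/e; daf-2 rsks-1. In daf-2 rsks-1 against rsks-1 the changes were 0.01 (adjusted p = 0.966) and 0.12 (adjusted p = 0.701). Between strains that both carry the daf-2 label, the first probe set fell by 0.58 in daf-2 rsks-1 against daf-2 (adjusted p = 0.0232), where the second changed by -0.51 (adjusted p = 0.0589). It passed in 4 alternatives of the limma fit, with adjusted p = 0.0411 as the lowest, when only the compared arrays were fitted. In aak-2 o/e; daf-2 rsks-1 against daf-2 rsks-1 the first rose by 0.49 (adjusted p = 0.0451) and the second changed by 0.32 (adjusted p = 0.224). That rise was lost in limma with no filter (adjusted p = 0.0502), with the replicate block (adjusted p = 0.0518) and with only the compared arrays (adjusted p = 0.0859). Where these probes lie relative to the mutations or the transgene is not given in the sources used here, so the arrays are named by their labels throughout.

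**Figure D1:**
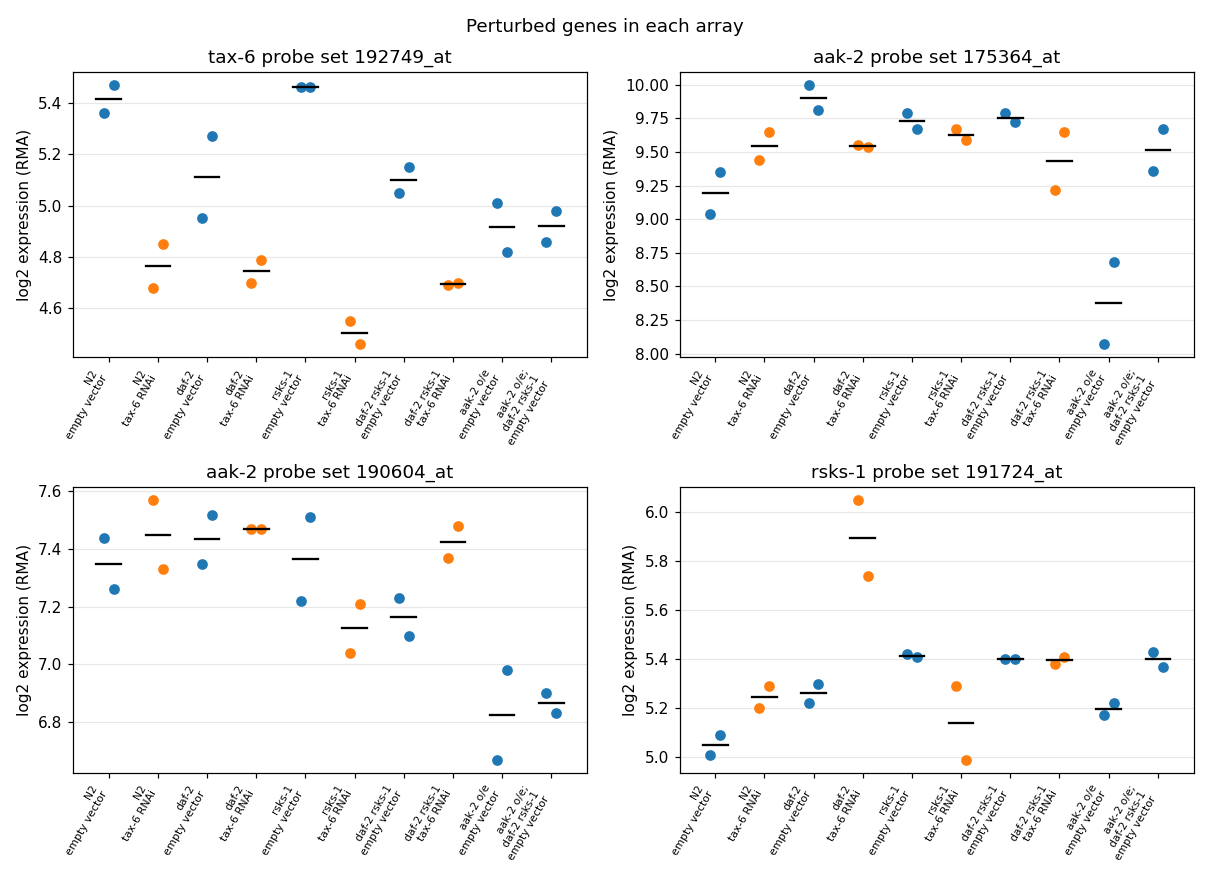
Log2 expression (RMA) of tax-6, aak-2 and rsks-1 probe sets in each of the 20 arrays, 1 point per array, with a line at the mean of the 2 arrays of a group. The lowest mean of the brighter aak-2 probe set, 8.37, belongs to the arrays labelled aak-2 o/e, against 9.19 in N2.

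**Figure D2:**
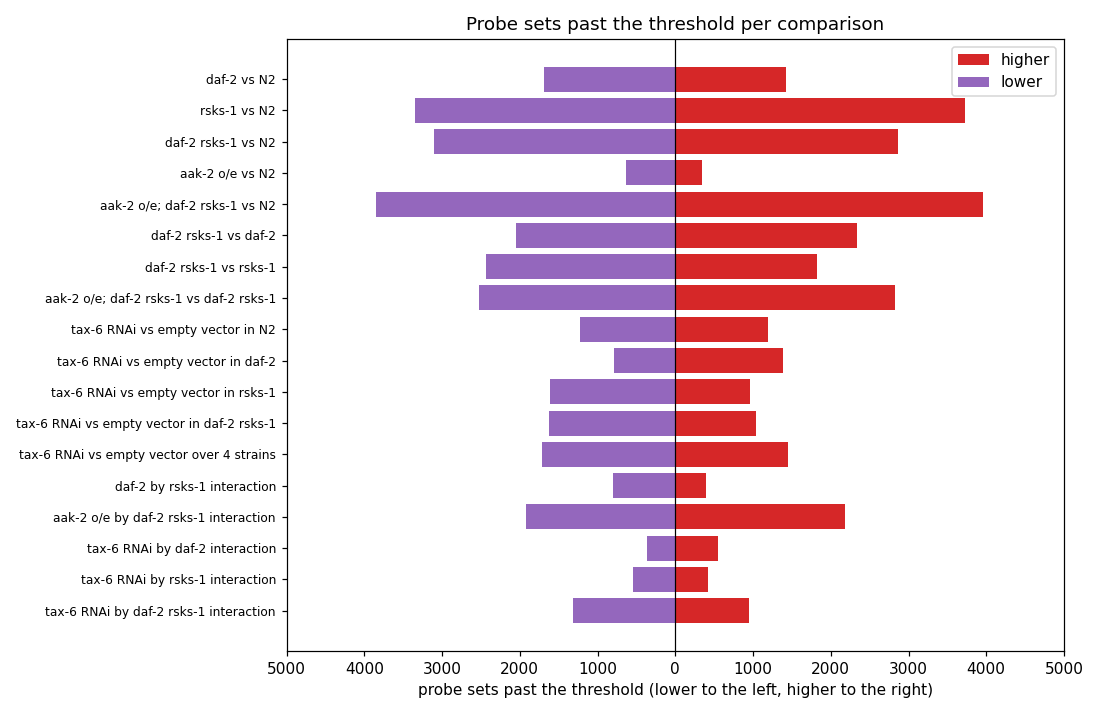
Number of probe sets past the threshold in each of the 18 comparisons, lower ones to the left of 0 and higher ones to the right. The comparison labelled aak-2 o/e; daf-2 rsks-1 against N2 has 7811 and aak-2 o/e against N2 has 972.

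The first question was what loss of insulin-like signalling changes. In the arrays labelled daf-2, sod-3, the mitochondrial superoxide dismutase, rose by 3.15 over N2 (SE 0.14, n = 2). The small heat shock genes hsp-12.6 and hsp-12.3 rose by 3.58 (SE 0.31) and 3.35 (SE 0.17), and the metallothionein gene mtl-1 by 2.55 (SE 0.21). The invertebrate lysozyme gene ilys-5 fell by 7.77 (SE 0.12) and ilys-2 fell by 4.01 (SE 0.14). The cathepsin B-like protease gene cpr-1 fell by 3.43 (SE 0.14), and ins-7, an insulin-like peptide gene, fell by 3.23 (SE 0.18). Another insulin-like peptide gene, ins-22, rose by 3.42 (SE 0.14). The gene clx-1 rose by 6.69 (SE 0.22). The N2 mean of hsp-12.6 (4.28) and the daf-2 mean of ilys-2 (3.72) lay under the filter value. For hsp-12.6 the 2 daf-2 arrays differed with an SD of 0.98.

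By lists, 13 of 22 genes known to be raised by the transcription factor DAF-16 under low insulin signalling rose in daf-2, 1 fell and 8 did not pass. Adjusted over the list alone the counts were again 13 and 1 (list adjusted p = 2.07e-12; adjusted p = 0.0408 with an estimated correlation). Of 15 genes known to be lowered in that state, 6 fell, among them dod-23 (fell by 2.74, SE 0.11) and dod-22 (fell by 3.15, SE 0.17), and 3 rose; adjusted over the list alone 8 fell. That list passed at adjusted p = 0.000871, and not at adjusted p = 0.192 with an estimated correlation. Sugar metabolism genes of glycolysis, gluconeogenesis and the glyoxylate cycle rose in 10 of 24 cases and fell in 0. The trehalose synthase gene tps-1 rose by 1.36 (SE 0.16), the gluconeogenic pck-1 by 0.76 (SE 0.11) and the glyoxylate gene icl-1 by 0.79 (SE 0.12); adjusted over the list alone 12 rose (adjusted p = 2.01e-05; adjusted p = 0.0408 with an estimated correlation). Intestine markers fell in 9 of 17 cases and rose in 1, with the filament gene ifb-2 lower (fell by 1.77, SE 0.14) and the peptide transporter pept-1 lower (fell by 1.26, SE 0.12). Adjusted over the list alone 10 intestine markers fell (adjusted p = 6.52e-07; adjusted p = 0.0408 with an estimated correlation).

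Yolk genes of the vitellogenin list fell in 3 of 5 cases in daf-2, most in vit-1 (fell by 2.27, SE 0.18), and in 4 cases adjusted over the list alone (adjusted p = 0.00111; adjusted p = 0.195 with an estimated correlation). Body wall muscle markers fell in 12 of 20 cases and rose in 2, by either count; the troponin I gene unc-27 fell by 1.12 (SE 0.14) and the alpha-actinin gene atn-1 fell by 0.98 (SE 0.11) (adjusted p = 6.69e-05; adjusted p = 0.268 with an estimated correlation). Cuticle collagens fell in 25 of 142 cases and rose in 6, with the same counts adjusted over the list alone (adjusted p = 0.00042; adjusted p = 0.478 with an estimated correlation). In all, 3114 probe sets passed the limma test, 1429 higher and 1685 lower. Without replicate 1 of daf-2 the count was 1854, and without replicate 1 of N2 it was 1881. Of 36 lists, 17 passed, and 3 did so with an estimated correlation too.

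The S6 kinase comparison gave the widest changes of the single mutants. In the arrays labelled rsks-1, the C-type lectin genes rose over N2, clec-61 by 5.04 (SE 0.14, n = 2) and clec-60 by 3.35 (SE 0.12), the saposin-like spp-12 by 4.15 (SE 0.17), and the antimicrobial peptide gene fipr-16 by 4.24 (SE 0.18). The protease gene try-13 rose by 4.97 (SE 0.17). The lipase-related lips-11 fell by 3.77 (SE 0.18), and the lysozyme gene lys-10 fell by 2.08 (SE 0.16). Of the 10 groups, N2 on empty vector had the highest lys-10 mean (7.05). The gene drd-10 fell by 2.76 (SE 0.38), but its 2 N2 arrays differed with an SD of 1.39. The cyclin E gene cye-1 fell by 1.35 (SE 0.13). The N2 means of clec-61 (3.97), try-13 (3.88) and fipr-16 (3.78) lay under the filter value.

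Antimicrobial peptide genes rose in 23 of 34 cases in rsks-1 and fell in 1, or 24 and 1 adjusted over the list alone (adjusted p = 3.1e-10; adjusted p = 0.0458 with an estimated correlation). Neuropeptide genes of the flp family rose in 22 of 24 cases, with flp-9 up by 1.65 (SE 0.14) and flp-22 by 1.46 (SE 0.12); adjusted over the list alone 23 rose (adjusted p = 2.14e-11; adjusted p = 0.0458 with an estimated correlation). Neuron markers rose in 10 of 19 cases and fell in 1 by either count, led by the neuropeptide processing genes sbt-1 (1.21, SE 0.11), egl-3 (1.201, SE 0.13) and egl-21 (1.05, SE 0.13) (adjusted p = 0.00396; adjusted p = 0.0476 with an estimated correlation). Body wall muscle markers rose in 10 of 20 cases and fell in 0 by either count (adjusted p = 0.00396, and adjusted p = 0.318 with an estimated correlation). Collagens rose in 35 of 142 cases and fell in 4, or 33 and 3 adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.609 with an estimated correlation). Detoxification lists rose as well: cytochrome P450 genes in 30 of 61 cases against 3 falls (31 and 3 adjusted over the list alone; adjusted p = 7.4e-05; adjusted p = 0.0102 with an estimated correlation), and UDP-glucuronosyltransferase genes in 33 of 55 against 3, the same adjusted over the list alone (adjusted p = 1.85e-07; adjusted p = 0.0476 with an estimated correlation). Examples are cyp-35B1, which rose by 2.12 (SE 0.21), and ugt-6, which rose by 1.74 (SE 0.17). Fatty acid synthesis, desaturation and elongation genes rose in 13 of 21 cases and fell in 0 by either count, including the desaturases fat-7 (1.37, SE 0.20) and fat-3 (1.19, SE 0.14) (adjusted p = 0.000164; adjusted p = 0.0474 with an estimated correlation). The list of genes raised by DAF-16 rose in 18 of 22 cases by either count, with mtl-1 up by 2.59 (SE 0.21) (adjusted p = 5.4e-11; adjusted p = 0.0367 with an estimated correlation).

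Mitochondrial ribosomal protein genes fell in 42 of 54 cases in rsks-1 and rose in 0; mrps-2 fell by 1.05 (SE 0.12) and mrpl-34 fell by 1.04 (SE 0.13). Adjusted over the list alone 44 fell (adjusted p = 4.73e-11; adjusted p = 0.093 with an estimated correlation). Germline and oocyte markers fell in 19 of 30 cases by either count, such as the synapsis gene syp-2 (fell by 1.04, SE 0.11) and the P granule gene pgl-1 (fell by 0.92, SE 0.11) (adjusted p = 5.7e-06; adjusted p = 0.0476 with an estimated correlation). Cell cycle and DNA replication genes also fell in 19 of 30 cases by either count (adjusted p = 5.7e-06; adjusted p = 0.0451 with an estimated correlation). Sperm markers rose in 9 of 14 cases and fell in 0, with the sperm phosphatase genes gsp-3 up by 1.18 (SE 0.19) and gsp-4 by 0.83 (SE 0.12); adjusted over the list alone 11 rose (adjusted p = 0.000882; adjusted p = 0.0401 with an estimated correlation). Among the 5 sperm markers read by probe sets with neither an x nor an s in their suffix, which Affymetrix uses for probes shared between transcripts, 2 rose, with a median of 0.42; this subset was chosen after the data were seen. Altogether 7079 probe sets passed, 3725 higher and 3354 lower. Of the lists 25 passed, 13 of them also with an estimated correlation.

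In the double mutant daf-2 rsks-1 against N2, sod-3 rose by 3.43 (SE 0.14, n = 2), hsp-12.3 by 3.50 (SE 0.17) and clx-1 by 5.11 (SE 0.22). The lysozyme gene ilys-5 fell by 8.07 (SE 0.12), the protease gene cpr-1 fell by 4.91 (SE 0.14) and ins-7 fell by 3.39 (SE 0.18). The nicotinic receptor subunit gene unc-38 rose by 3.71 (SE 0.14), and icmt-1, which encodes a methyltransferase of prenylated proteins, by 4.59 (SE 0.21). Genes raised by DAF-16 rose in 19 of 22 cases by either count (adjusted p = 4.35e-16; adjusted p = 0.0148 with an estimated correlation). Genes of sugar metabolism rose in 13 of 24 cases by either count, pck-1 by 1.36 (SE 0.11) (adjusted p = 1.98e-05; adjusted p = 0.0391 with an estimated correlation). Cytochrome P450 genes rose in 25 of 61 cases and fell in 8, with cyp-34A8 up by 1.95 (SE 0.12) and cyp-13A5 down (fell by 2.23, SE 0.18); adjusted over the list alone the counts were 26 and 9 (adjusted p = 0.000694; adjusted p = 0.0148 with an estimated correlation). The flp neuropeptide genes rose in 22 of 24 cases by either count (adjusted p = 6.11e-13; adjusted p = 0.0511 with an estimated correlation). Intestine markers fell in 9 of 17 cases and rose in 1 by either count, with a median of -0.76 (adjusted p = 0.000209, and adjusted p = 0.0821 with an estimated correlation). Germline and oocyte markers fell in 13 of 30 cases and rose in 1, or 14 and 1 adjusted over the list alone (adjusted p = 0.000694, and adjusted p = 0.14 with an estimated correlation). Muscle markers rose in 11 of 20 cases and fell in 3, or 12 and 3 adjusted over the list alone (adjusted p = 0.00741, and adjusted p = 0.546 with an estimated correlation). Neuron markers rose in 8 of 19 cases and fell in 2 by either count (adjusted p = 0.0126, and adjusted p = 0.098 with an estimated correlation). Cuticle collagens rose in 51 of 142 cases and fell in 2, or 52 and 3 adjusted over the list alone (adjusted p = 6.8e-06, and adjusted p = 0.588 with an estimated correlation). Cell cycle genes fell in 16 of 30 cases, or 19 adjusted over the list alone, and cye-1 fell by 1.09 (SE 0.13) (list adjusted p = 0.000303; adjusted p = 0.0821 with an estimated correlation). In total 5968 probe sets passed, 2869 higher and 3099 lower, or 3211 higher and 2742 lower after cyclic loess, and 3920 passed without replicate 2 of daf-2 rsks-1. Of the lists 17 passed, 3 of them with an estimated correlation too.

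The effect of the added rsks-1 mutation was read from daf-2 rsks-1 against daf-2 alone. The collagen genes col-101 and col-143 rose by 2.57 (SE 0.14, n = 2) and 2.30 (SE 0.12), the muscle myosin light chain gene mlc-3 by 1.32 (SE 0.13), and flp-12 by 1.17 (SE 0.12). The purine synthesis gene pfas-1 rose by 3.34 (SE 0.14) and the sphingomyelinase gene asm-2 by 3.26 (SE 0.15). Collagens rose in 64 of 142 cases and fell in 0, or 70 and 0 adjusted over the list alone (adjusted p = 1.2e-14; adjusted p = 0.221 with an estimated correlation). Muscle markers rose in 14 of 20 cases and fell in 1, or 17 and 1 adjusted over the list alone (adjusted p = 4.49e-10; adjusted p = 0.14 with an estimated correlation). The flp genes rose in 19 of 24 cases, or 21 adjusted over the list alone (adjusted p = 3.46e-13; adjusted p = 0.0644 with an estimated correlation). Neuron markers rose in 6 of 19 cases and fell in 2 by either count (adjusted p = 0.0342, and adjusted p = 0.191 with an estimated correlation). Germline and oocyte markers fell in 6 of 30 cases and rose in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.00467, and adjusted p = 0.215 with an estimated correlation). Yolk genes rose in 4 of 5 cases by either count, vit-1 by 1.43 (SE 0.18) (adjusted p = 0.00579; adjusted p = 0.192 with an estimated correlation). Cytochrome P450 genes rose in 26 of 61 cases and fell in 3, or 27 and 4 adjusted over the list alone (adjusted p = 0.000466; adjusted p = 0.0222 with an estimated correlation). Histone genes fell in 15 of 34 cases and rose in 2, or 16 and 4 adjusted over the list alone (adjusted p = 0.00657; adjusted p = 0.327 with an estimated correlation). There were 4380 probe sets past the threshold, 2336 higher and 2044 lower, and 53.3% were higher against 65.7% after cyclic loess. The count was 2730 without replicate 2 of daf-2, and 2911 and 2641 without replicate 1 and replicate 2 of daf-2 rsks-1.

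The effect of the added daf-2 mutation was read from daf-2 rsks-1 against rsks-1 alone. The lysozyme gene ilys-5 fell by 8.53 (SE 0.12, n = 2), cpr-1 fell by 6.11 (SE 0.14), the aspartic protease gene asp-17 fell by 5.02 (SE 0.15) and the desaturase gene fat-7 fell by 4.04 (SE 0.20). The antimicrobial peptide gene cnc-7 fell by 4.50 (SE 0.18), while sod-3 rose by 2.395 (SE 0.14). Intestine markers fell in 14 of 17 cases and rose in 0, or 14 and 1 adjusted over the list alone (adjusted p = 5.87e-10; adjusted p = 0.0378 with an estimated correlation). Cuticle collagens rose in 17 of 142 cases and fell in 9, or 16 and 9 adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.687 with an estimated correlation). C-type lectin genes fell in 67 of 154 cases and rose in 7, or 72 and 8 adjusted over the list alone (adjusted p = 4.04e-10; adjusted p = 0.108 with an estimated correlation). Antimicrobial peptide genes fell in 17 of 34 cases and rose in 1, or 18 and 2 adjusted over the list alone (adjusted p = 2.67e-07; adjusted p = 0.108 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 40 of 54 cases, mrpl-19 by 0.85 (SE 0.13) and mrpl-12 by 0.82 (SE 0.12); adjusted over the list alone 43 rose (adjusted p = 3.3e-14; adjusted p = 0.108 with an estimated correlation). Sperm markers fell in 10 of 14 cases and rose in 2 by either count, with gsp-4 lower (fell by 1.33, SE 0.12) and spe-9 higher (1.87, SE 0.17) (adjusted p = 0.000971; adjusted p = 0.0581 with an estimated correlation). Of the 5 with probe sets of neither suffix, 1 rose and 2 fell, with a median of 0.03. The count was 4263, with 1828 higher and 2435 lower, and 2552 without replicate 2 of daf-2 rsks-1.

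The difference between the effect of rsks-1 in daf-2 and its effect in N2 was tested directly. The difference was -4.79 for try-13 (SE 0.24), -4.19 for spp-12 (SE 0.24), -4.02 for fipr-16 (SE 0.26) and -3.90 for clec-61 (SE 0.20). The N2 means of fipr-16 and clec-61 lay under the filter value. For try-13 the means of N2 (3.88), daf-2 (3.69) and daf-2 rsks-1 (3.87) did, and only that of rsks-1 lay above it. Positive differences were those of the collagen genes col-159 (2.56, SE 0.23) and col-160 (2.46, SE 0.21), damt-1 (2.75, SE 0.19) and pfas-1 (2.44, SE 0.20). In all, 1202 probe sets passed, 401 with a more positive effect and 801 with a more negative one. Across all tested probe sets, the rsks-1 effect in N2 and in daf-2, which share no array, correlated at Pearson r = 0.607 (Spearman rho 0.667), and of 3138 probe sets past the threshold in both, 3025 went the same way. For the daf-2 effect in N2 and in rsks-1 the values were r = 0.593 (rho 0.494) and 1564 of 1663.

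The arrays labelled aak-2 o/e, which address the AMPK arm, differed least from N2. In these arrays pud-3 rose by 2.41 (SE 0.18, n = 2), pud-4 by 1.43 (SE 0.15) and the acyl-CoA dehydrogenase gene acdh-1 by 1.26 (SE 0.18). The acid ceramidase gene asah-1 rose by 1.07 (SE 0.13) and the lysosomal lipase gene lipl-2 by 1.00 (SE 0.16). The lysozyme genes ilys-2 (fell by 2.14, SE 0.14), lys-10 (fell by 1.69, SE 0.16) and ilys-3 (fell by 1.38, SE 0.23) were lower, as was hsp-70 (fell by 1.64, SE 0.21). Among the 10 groups, N2 on empty vector had the highest means of ilys-2 (7.73) and lys-10 (7.05). Lower levels of these genes than in N2 were thus not particular to aak-2 o/e. The neuropeptide-like gene nlp-39 fell by 2.08 (SE 0.14), and drd-10 fell by 3.12 (SE 0.38), against the same N2 arrays that differed with an SD of 1.39. Of the 36 lists, 1 passed, that of RNAi and small RNA machinery, in which the Argonaute gene alg-1 rose by 0.49 (SE 0.13) and the others did not pass, with 1 of 29 risen and 0 adjusted over the list alone (list adjusted p = 0.0325; adjusted p = 0.756 with an estimated correlation). The alg-1 call had adjusted p = 0.0581 in limma when only the compared arrays were fitted. The count was 972, with 338 higher and 634 lower. It was 527 and 427 without replicate 1 and replicate 2 of aak-2 o/e, and 325 and 485 without replicate 1 and replicate 2 of N2.

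In the arrays labelled aak-2 o/e; daf-2 rsks-1, cuticle genes rose over N2: dpy-5 by 5.97 (SE 0.18, n = 2), col-90 by 5.18 (SE 0.17), sqt-1 by 4.05 (SE 0.15), col-48 by 3.50 (SE 0.13), dpy-7 by 2.97 (SE 0.15) and rol-6 by 2.86 (SE 0.20), all collagen genes. The junction gene ajm-1, a marker of epithelia, rose by 1.69 (SE 0.14). Sperm genes were also higher, with msd-2 up by 3.06 (SE 0.32) and gsp-3 by 1.97 (SE 0.19). The lysozyme gene ilys-5 fell by 4.83 (SE 0.12), the protease genes cpr-5 and asp-17 fell by 3.97 (SE 0.16) and fell by 3.72 (SE 0.15), and ins-7 fell by 3.87 (SE 0.18). The N2 means of dpy-5 (4.25), col-90 (4.25), sqt-1, col-48 and dpy-7 lay under the filter value.

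Collagens rose in 90 of 142 cases and fell in 7 in this strain against N2, or 92 and 7 adjusted over the list alone (adjusted p = 1.16e-16; adjusted p = 0.204 with an estimated correlation). Hypodermis and seam markers rose in 10 of 16 cases and fell in 2 by either count (adjusted p = 0.000277; adjusted p = 0.0468 with an estimated correlation). Of the 16 markers 3 are also in the collagen list. Among the other 13, a subset chosen after the data were seen, 8 rose and 1 fell, with a median of 0.90. Sperm markers rose in 9 of 14 cases and fell in 0, or 11 and 0 adjusted over the list alone (adjusted p = 0.000277; adjusted p = 0.0322 with an estimated correlation). Beside these groups, a list of 35 moult and larval cuticle genes, written after the collagen result was seen, rose in 31 cases with a median of 2.31. Genes raised by DAF-16 rose in 19 of 22 cases by either count, dod-6 by 2.18 (SE 0.11) (adjusted p = 3.03e-11; adjusted p = 0.0322 with an estimated correlation). Genes lowered in the same state fell in 11 of 15 cases and rose in 3 by either count, dod-24 lower (fell by 3.70, SE 0.17) (adjusted p = 4.63e-05; adjusted p = 0.0938 with an estimated correlation). Germline and oocyte markers fell in 20 of 30 cases and rose in 2 by either count, puf-3 lower (fell by 1.36, SE 0.11) (adjusted p = 4.63e-05; adjusted p = 0.126 with an estimated correlation). Muscle markers rose in 13 of 20 cases and fell in 0, or 16 and 0 adjusted over the list alone (adjusted p = 0.000544, and adjusted p = 0.33 with an estimated correlation). The flp genes rose in 18 of 24 cases and fell in 0, or 20 and 0 adjusted over the list alone (adjusted p = 3.84e-07, and adjusted p = 0.129 with an estimated correlation). Intestine markers fell in 7 of 17 cases and rose in 2, or 7 and 3 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.204 with an estimated correlation). The comparison with N2 had 7811 probe sets past the threshold, 3961 higher and 3850 lower, and 17 lists, of which 3 also passed with an estimated correlation.

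Measured against daf-2 rsks-1, the arrays labelled aak-2 o/e; daf-2 rsks-1 had dpy-5 up by 5.63 (SE 0.18, n = 2), col-90 by 5.004 (SE 0.17) and sqt-1 by 3.95 (SE 0.15). Genes of the major sperm protein family followed, msp-78 by 4.05 (SE 0.20) and msp-31 by 3.91 (SE 0.17). The xanthine dehydrogenase gene xdh-1 fell by 2.63 (SE 0.15), the serotonin receptor gene ser-4 fell by 1.88 (SE 0.20) and ugt-63 fell by 2.12 (SE 0.14). The daf-2 rsks-1 means of col-90 (4.43) and sqt-1 (4.13), and the mean of xdh-1 (4.17) in the other strain, lay under the filter value. Collagens rose in 70 of 142 cases and fell in 17, or 74 and 17 adjusted over the list alone (adjusted p = 4.14e-11; adjusted p = 0.554 with an estimated correlation). Hypodermis and seam markers rose in 9 of 16 cases and fell in 2, or 10 and 2 adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.056 with an estimated correlation). Among the 13 of them outside the collagen list, 7 rose and 1 fell, with a median of 0.48. Markers of germline and oocytes fell in 11 of 30 cases and rose in 2, or 12 and 3 adjusted over the list alone (adjusted p = 0.0331, and adjusted p = 0.554 with an estimated correlation). Sperm markers rose in 9 of 14 cases and fell in 2 by either count (adjusted p = 0.000648; adjusted p = 0.0285 with an estimated correlation), and of the 5 with probe sets of neither suffix 2 rose and 1 fell. Cytochrome P450 genes fell in 21 of 61 cases and rose in 5, or 24 and 7 adjusted over the list alone (adjusted p = 0.00495; adjusted p = 0.0285 with an estimated correlation). Lysosomal protease and V-ATPase genes fell in 20 of 49 cases and rose in 2, or 22 and 2 adjusted over the list alone (adjusted p = 0.00176; adjusted p = 0.342 with an estimated correlation). The 35 moult and larval cuticle genes rose in 31 cases and fell in 1. In this comparison 5350 probe sets passed, 2827 higher and 2523 lower.

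The effect of the aak-2 o/e label differed between the daf-2 rsks-1 and N2 backgrounds at 4100 probe sets, 2184 more positive and 1916 more negative in daf-2 rsks-1. The differences were 5.52 for dpy-5 (SE 0.26), 5.01 for col-90 (SE 0.24) and 4.65 for ces-2 (SE 0.19), a bZIP transcription factor gene, and -2.52 for xdh-1 (SE 0.21) and -2.43 for ser-4 (SE 0.28). The effect of the label in N2 compares low signals for dpy-5, col-90 and xdh-1. In both N2 and aak-2 o/e, dpy-5 (4.25 and 4.37), col-90 (4.25 and 4.24) and xdh-1 (4.07 and 3.96) had means under the filter value. The means of col-90 in daf-2 rsks-1 (4.43) and of xdh-1 in aak-2 o/e; daf-2 rsks-1 (4.17) lay under it too. Across probe sets both effects correlated at r = -0.124 (rho -0.093), and of 472 past the threshold in both, 163 went the same way and 309 opposite ways.

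**Figure D3:**
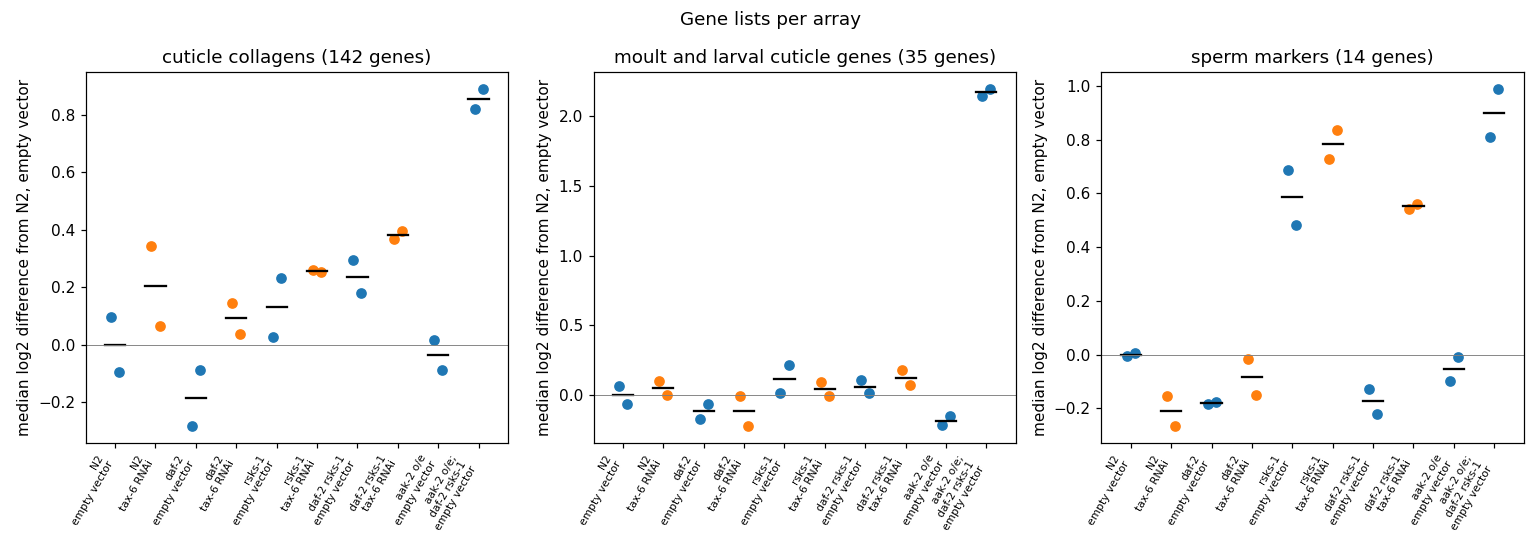
Median log2 difference from the mean of N2 on empty vector over the genes of a list, 1 point per array (blue empty vector, orange tax-6 RNAi), with a line at the mean of 2 arrays. Over 35 moult and larval cuticle genes the arrays labelled aak-2 o/e; daf-2 rsks-1 stand apart from the others, and sperm markers are higher in those arrays, in both rsks-1 groups and in daf-2 rsks-1 under tax-6 RNAi.

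The second part of the design asked what tax-6 RNAi changes in each strain. In N2, gsto-1, an omega-class glutathione S-transferase, rose by 4.29 (SE 0.15, n = 2), the saposin-like spp-12 by 4.201 (SE 0.17), the lipase gene fil-1 by 3.28 (SE 0.13) and ugt-18 by 2.91 (SE 0.22). The haem transport gene hrg-3 rose by 3.76 (SE 0.41), from an empty-vector mean of 3.04, under the filter value. The collagen gene col-183 fell by 2.83 (SE 0.13), the antimicrobial peptide gene cnc-7 fell by 2.92 (SE 0.18) and lips-11 fell by 4.13 (SE 0.18). Lysosomal protease and V-ATPase genes rose in 17 of 49 cases and fell in 0, or 22 and 2 adjusted over the list alone, with vha-6 up by 1.65 (SE 0.13) (adjusted p = 1.62e-06; adjusted p = 0.171 with an estimated correlation). Intestine markers rose in 7 of 17 cases and fell in 1, or 8 and 3 adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.24 with an estimated correlation). The flp genes rose in 9 of 24 cases and fell in 0, or 11 and 0 adjusted over the list alone (adjusted p = 0.000454, and adjusted p = 0.226 with an estimated correlation). Collagens rose in 29 of 142 cases and fell in 2, or 32 and 3 adjusted over the list alone (adjusted p = 1.41e-06, and adjusted p = 0.363 with an estimated correlation). Markers of germline and oocytes fell in 5 of 30 cases and rose in 0 by either count (adjusted p = 9e-04, and adjusted p = 0.193 with an estimated correlation). Yolk genes fell in 3 of 5 cases by either count (adjusted p = 0.0132, and adjusted p = 0.225 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 23 of 54 cases and fell in 0, or 29 and 1 adjusted over the list alone, with mrps-23 up by 1.15 (SE 0.12) (adjusted p = 1.27e-08; adjusted p = 0.193 with an estimated correlation). Antimicrobial peptide genes fell in 13 of 34 cases and rose in 2, or 14 and 3 adjusted over the list alone (adjusted p = 0.000116; adjusted p = 0.193 with an estimated correlation). Of 36 lists 19 passed camera, and 0 did with an estimated correlation, where 6 had an unadjusted p under 0.05. The count was 2422, with 1198 higher and 1224 lower, or 1278 higher and 1237 lower after cyclic loess; it was 1477 and 1347 without replicate 1 and replicate 2 of N2 on empty vector, 1558 without replicate 1 of N2 under RNAi, and 1274 when only the compared arrays were fitted.

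In daf-2, tax-6 RNAi raised the protease gene cpr-2 by 5.59 (SE 0.14, n = 2), gsto-1 by 4.17 (SE 0.15) and the arginine kinase gene argk-1 by 3.02 (SE 0.18). The gene pud-4 fell by 2.65 (SE 0.15), sysm-1 fell by 2.58 (SE 0.16) and dod-24 fell by 1.84 (SE 0.18). Collagens rose in 36 of 142 cases and fell in 1, col-159 by 2.56 (SE 0.16) and col-160 by 2.34 (SE 0.15); adjusted over the list alone 44 rose and 2 fell (adjusted p = 9.51e-09; adjusted p = 0.425 with an estimated correlation). Fatty acid oxidation and lipase genes rose in 15 of 47 cases and fell in 1, lipl-1 by 2.03 (SE 0.13) and hacd-1 by 1.39 (SE 0.12); adjusted over the list alone 17 rose and 2 fell (adjusted p = 0.00013; adjusted p = 0.225 with an estimated correlation). Intestine markers rose in 8 of 17 cases and fell in 3, or 9 and 3 adjusted over the list alone (adjusted p = 0.00289; adjusted p = 0.225 with an estimated correlation). The flp genes rose in 6 of 24 cases and fell in 0, or 8 and 0 adjusted over the list alone (adjusted p = 0.000214, and adjusted p = 0.248 with an estimated correlation). Markers of germline and oocytes fell in 4 of 30 cases and rose in 1, or 5 and 1 adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.225 with an estimated correlation). Of the lists 19 passed camera, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. A total of 2170 probe sets passed, 1382 higher and 788 lower. The count was 1288 and 995 without replicate 1 and replicate 2 of daf-2 on empty vector, and 743 without replicate 1 of daf-2 under RNAi.

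In rsks-1, tax-6 RNAi raised C-type lectin genes, clec-53 by 5.15 (SE 0.17, n = 2), clec-9 by 4.24 (SE 0.21) and clec-70 by 3.99 (SE 0.13), while col-183 fell by 4.40 (SE 0.13) and the antimicrobial peptide genes fipr-26 and cnc-6 fell by 2.77 (SE 0.14) and fell by 2.57 (SE 0.15). The metallothionein gene mtl-1 fell by 2.03 (SE 0.21). Lectins rose in 49 of 154 cases and fell in 14, or 57 and 16 adjusted over the list alone (adjusted p = 4.14e-11; adjusted p = 0.231 with an estimated correlation). Genes raised by DAF-16 fell in 11 of 22 cases and rose in 0, or 13 and 1 adjusted over the list alone (adjusted p = 6.85e-05; adjusted p = 0.231 with an estimated correlation). Yolk genes fell in 4 of 5 cases, or 5 adjusted over the list alone (adjusted p = 0.0018; adjusted p = 0.231 with an estimated correlation). Collagens rose in 15 of 142 cases and fell in 7 by either count (adjusted p = 0.00202, and adjusted p = 0.689 with an estimated correlation). Camera called 11 lists, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Past the threshold were 2577 probe sets, 961 higher and 1616 lower, or 1433 when only the compared arrays were fitted. The higher share was 37.3%, against 48.9% after cyclic loess.

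In daf-2 rsks-1, cpr-2 rose by 6.69 (SE 0.14, n = 2), the largest of the 4 strains, the aquaglyceroporin gene aqp-1 by 3.15 (SE 0.19), and the sperm protein genes msp-78 and msp-36 by 2.59 (SE 0.20) and 2.47 (SE 0.17). The collagen gene col-183 fell by 3.61 (SE 0.13), and pud-3 and pud-4 fell by 2.43 (SE 0.18) and fell by 2.36 (SE 0.15). Sperm markers rose in 8 of 14 cases and fell in 0, or 9 and 0 adjusted over the list alone (adjusted p = 0.000125, and adjusted p = 0.0213 with an estimated correlation). Of the 5 with probe sets of neither suffix 1 rose, with a median of 0.05, against 0.49 for all 14. Muscle markers fell in 8 of 20 cases and rose in 1 by either count, mlc-1 lower (fell by 0.80, SE 0.12) (adjusted p = 0.00461; adjusted p = 0.59 with an estimated correlation). Intestine markers rose in 7 of 17 cases and fell in 2, or 8 and 2 adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.57 with an estimated correlation). Yolk genes fell in 2 of 5 cases by either count (adjusted p = 0.0126, and adjusted p = 0.57 with an estimated correlation). Of the lists 5 passed, 1 of them also with an estimated correlation. In this strain 2667 probe sets passed, 1040 higher and 1627 lower. Without replicate 2 of daf-2 rsks-1 on empty vector 754 did, and 1140 and 1764 without replicate 1 and replicate 2 under RNAi.

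Over the 4 strains, the average effect of tax-6 RNAi raised cpr-2 by 4.68 (SE 0.40, n = 8 arrays per arm), gsto-1 by 3.97 (SE 0.18), the cathepsin A-like gene ctsa-4.1 by 2.94 (SE 0.12), the metallopeptidase gene nep-22 by 2.90 (SE 0.15) and the enoyl-CoA hydratase gene ech-9 by 2.62 (SE 0.17). The collagen gene col-183 fell by 3.16 (SE 0.24), the chitinase gene cht-1 fell by 0.70 (SE 0.07), cdr-4 fell by 0.77 (SE 0.07) and the metallopeptidase gene nas-5 fell by 1.05 (SE 0.09). Mitochondrial ribosomal protein genes rose in 30 of 54 cases and fell in 0, or 33 and 0 adjusted over the list alone (adjusted p = 3.39e-10; adjusted p = 0.177 with an estimated correlation). Lysosomal protease and V-ATPase genes rose in 20 of 49 cases and fell in 4, vha-6 by 1.47 (SE 0.07) and cpr-8 by 2.11 (SE 0.11); adjusted over the list alone 20 rose and 5 fell (adjusted p = 0.000517; adjusted p = 0.177 with an estimated correlation). Intestine markers rose in 7 of 17 cases and fell in 3, or 9 and 4 adjusted over the list alone (adjusted p = 0.00677, and adjusted p = 0.169 with an estimated correlation). Germline and oocyte markers fell in 6 of 30 cases and rose in 0 by either count (adjusted p = 0.00113, and adjusted p = 0.177 with an estimated correlation). Collagens rose in 43 of 142 cases and fell in 5, or 54 and 5 adjusted over the list alone (adjusted p = 1.58e-09, and adjusted p = 0.381 with an estimated correlation). Yolk genes fell in 3 of 5 cases, vit-5 lower (fell by 0.49, SE 0.05), or 4 adjusted over the list alone (adjusted p = 0.000517; adjusted p = 0.169 with an estimated correlation). Autophagy genes fell in 6 of 24 cases and rose in 1, or 8 and 2 adjusted over the list alone; the beclin gene bec-1 fell by 0.32 (SE 0.07) (adjusted p = 0.00422; adjusted p = 0.177 with an estimated correlation). Genes raised by DAF-16 fell in 6 of 22 cases and rose in 1, or 7 and 3 adjusted over the list alone (adjusted p = 0.0405; adjusted p = 0.566 with an estimated correlation, and 0.0627 with the mean of all probe sets of a gene). Camera called 14 lists over the 4 strains, and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05. The count was 3166, with 1452 higher and 1714 lower, or 1714 higher and 1489 lower after cyclic loess. It was 5197 when all 20 arrays were fitted and the 4 effects averaged. In the fit of the 8 group means, with 3 residual degrees of freedom, 343 probe sets passed, 228 higher and 115 lower, and bec-1 had adjusted p = 0.125 in limma. Past the threshold in every one of the 4 strains were 163 probe sets higher and 61 lower, against 0.32 and 0.49 expected if the strains were independent. The 4 comparisons share 1 estimate of the spread per probe set, which can raise the overlap without a shared effect.

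**Figure D4:**
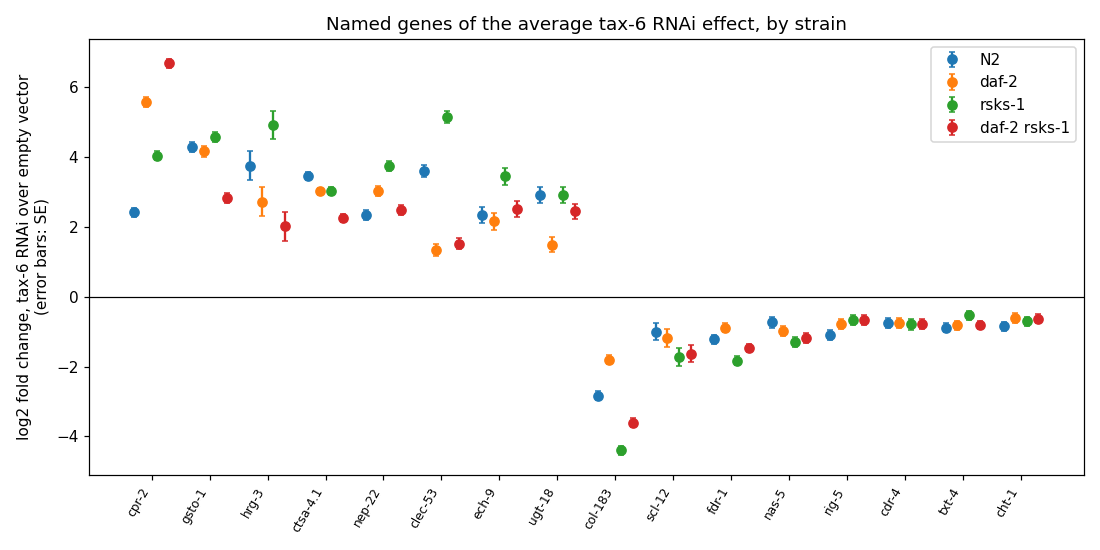
Log2 change under tax-6 RNAi over empty vector in 4 strains, with the standard error, for the 8 genes with the largest average rise and the 8 with the largest average fall among those past the threshold whose 8 RNAi arrays lay all above or all below the 8 empty-vector arrays. Larger falls without this separation are not drawn, nor are genes with only a sequence name, such as T12D8.5 (average change -3.07). The change of cpr-2 runs from 2.42 in N2 to 6.69 in daf-2 rsks-1, and that of col-183 from -1.80 in daf-2 to -4.40 in rsks-1; the empty-vector means of hrg-3 lay under the filter value.

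Whether tax-6 RNAi acts differently between strains was tested as an interaction with N2 as the reference. With daf-2, 913 probe sets passed, 549 more positive and 364 more negative. Among them cpr-2 differed by 3.17 (SE 0.19), cnc-7 by 3.41 (SE 0.26), spp-12 by -3.50 (SE 0.24) and fil-1 by -2.82 (SE 0.19). This count was 592 when only the compared arrays were fitted, and 378, 298 and 381 without replicate 1 of daf-2 on empty vector, of daf-2 under RNAi and of N2 on empty vector. With rsks-1, 962 passed, 418 more positive and 544 more negative, for example clec-70 (2.81, SE 0.18), lips-11 (3.04, SE 0.25), asp-17 (-2.44, SE 0.21) and the lipase gene lipl-4 (-2.31, SE 0.23). Before RNAi, cnc-7 averaged 9.49 in N2 and 5.79 in daf-2, and lips-11 averaged 9.86 in N2 and 6.09 in rsks-1. Under RNAi in N2, cnc-7 averaged 6.56 and lips-11 5.73. How far these starting levels shaped the differences was not tested.

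The rsks-1 interaction count was 378 when only the compared arrays were fitted, 499 and 625 without replicate 1 and replicate 2 of N2 on empty vector, 562 without replicate 2 of N2 under RNAi and 605 without replicate 1 of rsks-1 on empty vector. Its more positive share was 43.5%, against 54.8% after cyclic loess. With daf-2 rsks-1, 2263 probe sets passed, 944 more positive and 1319 more negative, for example cpr-2 (4.27, SE 0.19), msp-78 (3.74, SE 0.28), lipl-2 (-2.73, SE 0.22) and clec-60 (-2.30, SE 0.17). That count was 1074 without replicate 2 of daf-2 rsks-1 on empty vector, 1232 without its replicate 1 under RNAi, 1139 without replicate 1 of N2 on empty vector and 1350 without replicate 2 of N2 under RNAi. Across genes, the RNAi effects of strain pairs, which share no array, correlated at r = 0.532 (rho 0.37) for N2 and rsks-1, 0.479 (rho 0.361) for daf-2 and daf-2 rsks-1, 0.439 (rho 0.37) for rsks-1 and daf-2 rsks-1, 0.427 (rho 0.255) for N2 and daf-2, 0.352 (rho 0.176) for daf-2 and rsks-1 and 0.201 (rho 0.085) for N2 and daf-2 rsks-1. These are 6 of 9 correlations computed.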

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

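The tests of male somatic markers, of splits of the RNAi labels within strains and of differences in effect between strains were chosen before their results were seen. The other tests of this part were chosen only after.

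The cuticle and moult genes of the arrays labelled aak-2 o/e; daf-2 rsks-1 form the first pattern: 31 of 35 moult and larval cuticle genes rose against daf-2 rsks-1, with a median of 2.096. After cyclic loess on top of RMA, the median change of 142 cuticle collagens was 0.43 (SE 0.128). This argues against differences between arrays that RMA left and loess removes. It cannot test a distortion made by RMA itself, and it was run on the collagens, not the moult genes. Against a single outlying array, the lower of the collagen medians with 1 array left out was 0.38 (SE 0.129). Larvae or late embryos among the collected animals stay open, since 10 larval timing and seam genes had a median of 0.21 (SE 0.277), with 4 risen and 2 fallen. The strain itself may also express these genes as adults, which was not tested.

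Sperm genes in some groups form the second pattern. The 14 sperm markers, none of them an msp gene, had a median of 0.59 (SE 0.173) in rsks-1 against N2. The rise thus reached beyond the msp genes. These markers are the list in which the rise was first seen. Their median is therefore no independent test of cross-hybridisation among near-identical msp genes. Probes shared within other sperm gene families stay open, since only 2 of the 5 markers with plain probe sets rose. Larvae that still make sperm stay undecided, as 35 moult genes had a small median of 0.11 (SE 0.078) in rsks-1 against N2, with 7 risen and 0 fallen. Males stay undecided as well. In the same comparison 7 male somatic markers had a median of 0.21 (SE 0.178) at a median level of 5.36, near the filter value. The male markers had medians of -0.273 in aak-2 o/e; daf-2 rsks-1 against daf-2 rsks-1 and 0.043 under tax-6 RNAi in daf-2 rsks-1, where sperm markers rose too. The moult genes had medians of 2.096 (31 risen, 1 fallen) and 0.041 (1 risen, 2 fallen) in these comparisons, in the same order. A longer period of sperm production in the mutants stays open too, as untested.

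Lower aak-2 in the arrays labelled aak-2 o/e is the third pattern. Against an exchange with arrays under tax-6 RNAi, the 163 probe sets raised by that RNAi in all 4 strains had a median of -0.029 (SE 0.037) in these arrays against N2. Of the 2 aak-2 probe sets, 0 were past the limma threshold and higher, and both were past it and lower. Probes outside the transgene may explain the absence of a rise, but where the probes lie is not given in the sources used here, and a mislabelled strain stays open. No biological explanation was tested.

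For tax-6 RNAi over the 4 strains, 1 of 100 splits of the RNAi labels within strains, the real one, gave as many as 3166 probe sets past the threshold. The highest of the other splits gave 64. Chance is thus unlikely for this count where the arrays are independent, but 100 splits cannot give less than 1 in 100. If the arrays of a group share a culture, whole groups are the unit, and limma on the 8 group means, added after the data were seen, called 343 probe sets. Of the 8 ways to exchange the foods of whole strains the other 7 gave 0, but 8 ways cannot give a p under 0.125.

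Several effects differed between strains by a direct test of the difference. The effect of rsks-1 differed between daf-2 and N2 at 1202 probe sets, with differences of 5.29 for drd-10 (SE 0.53), 2.75 for damt-1 (SE 0.19), -4.79 for try-13 (SE 0.24) and -4.19 for spp-12 (SE 0.24). The means of try-13 in N2, daf-2 and daf-2 rsks-1 lay under the filter value, and the drd-10 value rests on N2 arrays that differed with an SD of 1.39. The effect of the aak-2 o/e label differed between daf-2 rsks-1 and N2 at 4100 probe sets, by 5.52 for dpy-5 (SE 0.26), 5.01 for col-90 (SE 0.24), -2.52 for xdh-1 (SE 0.21) and -2.43 for ser-4 (SE 0.28), where the means of dpy-5, col-90 and xdh-1 in both N2 and aak-2 o/e lay under the filter value, as did those of col-90 in daf-2 rsks-1 and of xdh-1 in aak-2 o/e; daf-2 rsks-1. The tax-6 RNAi effect differed between daf-2 and N2 at 913 probe sets, by 3.49 for srlf-34 (SE 0.28), 3.41 for cnc-7 (SE 0.26), -3.50 for spp-12 (SE 0.24) and -2.82 for fil-1 (SE 0.19). Between rsks-1 and N2 it differed at 962, by 3.24 for drd-10 (SE 0.53), 3.04 for lips-11 (SE 0.25), -2.44 for asp-17 (SE 0.21) and -2.31 for lipl-4 (SE 0.23). This drd-10 value rests on the same N2 empty-vector arrays, and its mean of 4.3 in N2 under RNAi lay under the filter value. Between daf-2 rsks-1 and N2 it differed at 2263, by 4.27 for cpr-2 (SE 0.19), 3.87 for lips-11 (SE 0.25), -2.87 for spp-12 (SE 0.24) and -2.73 for lipl-2 (SE 0.22). On empty vector, lips-11 averaged 9.86 in N2, 6.09 in rsks-1 and 5.15 in daf-2 rsks-1, against 5.73 in N2 under RNAi. Similarly, cnc-7 averaged 9.49 in N2 and 5.79 in daf-2, against 6.56 in N2 under RNAi. The RNAi effects on these genes thus started from different levels. Without 1 array, the lowest counts of these tests were 815, 2910, 298, 499 and 1074, in the same order.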

How the results depend on the processing

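The fit without the arrays labelled aak-2 o/e; daf-2 rsks-1 and the fit of 8 group means were chosen only after the results were seen. All 18 counts stayed within 1.5 times under no filter, the filter at the 50th percentile, cyclic loess, the replicate block, and trend and robust moderation, and 14 of 14 did in the fit without that strain. When only the compared arrays were fitted, with fewer arrays to estimate the spread, 13 of 17 counts did. The others were those of tax-6 RNAi in N2 (1274) and in rsks-1 (1433) and its interactions with daf-2 (592) and rsks-1 (378). For the average RNAi effect, the mean of the 4 effects in a fit of all 20 arrays gave 5197. The fit of 8 group means, with 3 residual degrees of freedom, gave 343. The main fit and the fit of group means count differences of the RNAi effect between strains as spread. The fit of all 20 arrays does not. How much this moved the counts was not tested. In the fit of group means, 31 of 67 gene values were no longer past the threshold. With 1 array left out, where the lone array is assumed to vary like the other groups, 31 such fits moved their count by more than 1.5 times and 73 did not. The ranges were 1854 to 2336 for daf-2 against N2, 5368 to 5796 for rsks-1, 3920 to 4628 for daf-2 rsks-1, 325 to 527 for aak-2 o/e and 6074 to 6391 for aak-2 o/e; daf-2 rsks-1. They were 2641 to 3097 for daf-2 rsks-1 against daf-2, 2552 to 3465 against rsks-1, and 3749 to 3831 for aak-2 o/e; daf-2 rsks-1 against daf-2 rsks-1. For tax-6 RNAi they were 1347 to 1714 in N2, 743 to 1710 in daf-2, 1725 to 1924 in rsks-1, 754 to 2224 in daf-2 rsks-1 and 2615 to 3344 over the 4 strains. For the interactions they were 815 to 1150 (daf-2 by rsks-1), 2910 to 3517 (aak-2 o/e by daf-2 rsks-1), and, for tax-6 RNAi, 298 to 834 with daf-2, 499 to 856 with rsks-1 and 1074 to 2199 with daf-2 rsks-1. These fits use fewer arrays; why single arrays moved some counts and not others was not tested.

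Correlations between RNAi effects at the 50th-percentile filter were 0.473 for N2 and daf-2, 0.562 for N2 and rsks-1, 0.412 for daf-2 and rsks-1 and 0.55 for daf-2 and daf-2 rsks-1, and that of the daf-2 effects was 0.608. With no filter they were 0.322 for daf-2 and rsks-1, 0.445 for daf-2 and daf-2 rsks-1 and 0.581 for the daf-2 effects. The cause was not tested. With 1 array left out, values not past the threshold changed sign at 2 daf-2 probe sets and the dimmer aak-2 one. The dimmer daf-2 probe set ranged from -0.069 to 0.509 in daf-2 against N2, from -0.576 to 0.003 in daf-2 rsks-1 against N2, from -0.255 to 0.324 in aak-2 o/e; daf-2 rsks-1 against N2 and from -0.124 to 0.37 in daf-2 rsks-1 against rsks-1. The brighter one ranged from -0.193 to 0.447 and from -0.068 to 0.097 in the last 2, and aak-2 from -0.004 to 0.172 in daf-2 and from -0.13 to 0.156 in rsks-1 against N2. Of 940 gene values, 10 were no longer past the threshold with cyclic loess, 5 with no filter, 3 with the block and 4 with trend and robust moderation. When only the compared arrays were fitted, 40 were no longer past it and 832 kept their direction and side. Over the fits with 1 array left out, a gene value was counted once in each fit that left out an array of its comparison. By this count 264 were no longer past the threshold and 4485 kept their direction and side. For calls on lists, counted the same way, the numbers were 60 and 860. Of the calls on lists, 161 of 188 were lost with an estimated correlation. With the mean of all probe sets 2 were lost, for tax-6 RNAi over the 4 strains: genes raised by DAF-16 (adjusted p = 0.0627) and fatty acid oxidation (adjusted p = 0.0519). Signal over background limits what dim probe sets can show.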

Other observations

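The families in this part were tested only after the results were seen. They are groups of at least 10 genes that share a symbol prefix, in 13 comparisons. Of 1599 camera tests, 108 passed with the preset correlation and 0 passed with an estimated one as well, where 109 had an unadjusted p under 0.05. Every adjusted p of a family below is with an estimated correlation.

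Genes of the major sperm protein family (msp, 23 members) had medians of 1.60 in rsks-1 against N2 (22 rose; adjusted p = 0.246 with an estimated correlation), 3.25 in aak-2 o/e; daf-2 rsks-1 against daf-2 rsks-1 (23 rose; 0.203) and 1.73 under tax-6 RNAi in daf-2 rsks-1 (23 rose; 0.16). The msp median was -2.36 in daf-2 rsks-1 against rsks-1 (23 fell; adjusted p = 0.195) and -0.87 in daf-2 against N2 (21 fell; adjusted p = 0.897). These near-identical genes are read mostly by probe sets with the x suffix, so their values are not independent of each other. Neuropeptide-like protein genes (nlp, 49 members) had a median of 0.88 in rsks-1 against N2 (41 rose; adjusted p = 0.176) and 0.66 in daf-2 rsks-1 against daf-2 (36 rose; adjusted p = 0.208). Nucleoporin genes (npp, 25 members) had medians of -0.56 in rsks-1 against N2 (23 fell; adjusted p = 0.113) and -0.35 in daf-2 rsks-1 against daf-2 (14 fell; adjusted p = 0.208). Transthyretin-related genes (ttr, 34 members) had a median of 0.52 in rsks-1 against N2 (24 rose; adjusted p = 0.285).

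The list of calcineurin pathway genes passed in no comparison; under tax-6 RNAi over the 4 strains 2 of 9 rose and 3 fell, with a median of -0.04 (adjusted p = 0.342). Differences between replicates 1 and 2 correlated between groups at -0.357 to 0.328, with a median of 0.031 over 45 pairs, of which 14 lay above 0.1.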
